A study of Mus musculus with 10 samples.

How the data were processed

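Total RNA from mammary tumours of adult female mice aged 90 days was labelled with biotin and hybridised to Affymetrix mg_u74av2 oligonucleotide arrays, per the labels. The series concerns mice that carry the MMTV-PyMT transgene, in which a mouse mammary tumour virus promoter drives the polyomavirus middle T antigen in the mammary epithelium. There were 10 arrays. The titles of 9 of them name a strain, and the groups were taken from those names: FVBn (1 array) and ILn, LP, MOLF and NZB (2 arrays each, lettered A and B). The strain label itself gives FVB/Nj for all 10 arrays, so the groups rest on the titles alone. The title of 1 array names no strain, and that array entered no comparison. The titles call each of the 9 arrays a mix without stating what was mixed. Nothing in the labels says that the 2 arrays of a strain came from separate animals. P-values of probe sets therefore measure only the spread between these arrays, which may be technical. Those of the gene list test described below also rest on the spread between genes.

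The deposited values are probe set intensity values on a linear scale, 1 per probe set and array. The method that summarised probes into probe sets is not given in the sources used here. The mean intensity after leaving out the lowest and highest 2% of probe sets was 150.1 on each array except ILn A, where it was 500.2. Scaling of each array to a fixed trimmed mean gives such values, but no label or header records that step. The median deposited log2 intensity lay between 5.95 and 6.03 on 6 strain arrays, at 6.44 on MOLF A, at 6.40 on NZB B and at 7.77 on ILn A. Because these medians differed by more than 0.1, the 9 strain arrays were quantile normalized in R 4.3.3 with limma 3.58.1. The array with no strain name was set to the same distribution afterwards. Values under the 30th percentile, an intensity of 27.0 (4.75 on the log2 scale), were raised to it, and log2 was taken. The array holds 12488 probe sets, of which 66 controls were left out. Of the remaining 12422 probe sets, 9899 lay above the floor in at least 2 of the 9 arrays and were tested.

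Gene symbols came from the platform annotation, which gave 1 symbol to 10855 probe sets, several to 396 and none to 1237. Symbols were updated through Entrez identifiers, of which 10839 matched the RefSeq gene table of GRCm38.p6, a table used for names only. The tested set held 8787 probe sets with 1 symbol, for 7098 genes. A probe set at the floor in every array of a group has only a bound there, and such a fold is written as "at least". A single array at the floor also makes a fold an understatement. Where several probe sets measure a gene, the values are those of the probe set with the highest mean among those that qualified, and another probe set is mentioned where it differed in sign or in passing the test.

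Differences were tested with limma (lmFit, then eBayes with an intensity trend) in 1 model with a mean for each of the 5 strain names, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The model had 4 residual degrees of freedom, a median prior of 3.30 degrees of freedom and a median SD within strains of 0.337 on the log2 scale. There were 8 comparisons, counting a moderated F test over the 4 strains with 2 arrays. Each of these strains was set against the mean of the other 3 (so a fold need not hold against each of them), the mean of the 4 was set against FVBn, and ILn was set against NZB and LP against MOLF, pairs whose arrays share title dates. The single FVBn array was assumed to vary like the other groups. All groups shared 1 spread per probe set, yet the SD of the difference within a pair was 0.379 in ILn, 0.467 in LP, 0.863 in MOLF and 0.913 in NZB. P-values of the limma tests can therefore be too small where MOLF or NZB weighs most, and too large where ILn or LP does. The simulations below gave all groups the same spread too, so their shares hold only under that assumption. The number of arrays limits the precision of every value. In simulated arrays with the spread of these 9899 probe sets, 30.4% of changes of 1 log2 unit, 87.2% of changes of 2 and 97.9% of changes of 3 were recovered for LP against the other strains, with 7.4 false calls per run. For the 4 strains against FVBn the shares were 12.2%, 66.3% and 94.5%, with 5.4 false calls, and for LP against MOLF they were 17.3%, 68.4% and 93.9%, with 7.6 false calls.

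The named genes followed a fixed rule over probe sets with 1 symbol. For each strain against the others these were up to 8 genes each way with the largest differences among those past the test whose 2 arrays lay beyond all 6 arrays of the other 3 strains. For FVBn they were the 5 largest each way with the FVBn array beyond all 8 others, for the 2 pairs of strains the 3 largest each way without overlap, and for the F test the 5 smallest p-values. For each gene list past its test, up to 4 members past the probe set test were added, or else the 2 members with the smallest p, given as values. The groups, the comparisons, the filter, this rule, 19 gene lists and the alternatives, except where stated otherwise, were chosen before the data were examined.

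The lists cover tumour cell programmes and markers of other cell types in a tumour piece: proliferation, milk and alveolar differentiation, luminal epithelium, basal and myoepithelial cells, fibroblasts and matrix, adipocytes, T and NK cells, B and plasma cells, macrophages and myeloid cells, neutrophils and the acute phase, MHC and antigen presentation, interferon response, endothelium, skeletal muscle, erythroid cells, hypoxia and glycolysis, cholesterol and fatty acid synthesis, immediate early and heat shock genes, and metastasis-associated genes. Each list was tested with camera at a preset correlation of 0.01, with 1 probe set per gene, and adjusted over the lists within a comparison. Camera sets the genes of a list against the other genes, so with the preset correlation the genes largely act as replicates. Its p-values can then be very small with few arrays. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. For the muscle list in LP the adjusted p was 4.07e-27 in camera with the preset, 0.00419 with an estimated correlation and 8.82e-05 with fry. Of the 30 list calls, 15 held with an estimated correlation: the 7 calls of the interferon list, the 7 of the muscle list and that of the fibroblast list in ILn. In simulated data for LP against the other strains, with 30 genes per list, 20 of 20 lists shifted by 0.5 were recovered and 0 of 360 unshifted lists were called. The simulated genes varied independently of each other, while the estimated correlation within the antigen presentation list was 0.126. The simulation therefore does not give the rate of false calls for lists whose genes vary together. Other comparisons and shorter lists were not simulated. A list of 54 salivary gland genes was added after the leading genes had been seen. It held 20 genes whose values were then known, so its counts are not independent evidence.

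The titles give dates, which form 4 batches: the array with no strain name (batch 1), ILn A and NZB B (batch 2), LP A and MOLF A (batch 3), and FVBn B, ILn B, LP B, MOLF B and NZB A (batch 4). Comparisons were repeated with the date as a fixed block, within each batch that held the groups compared, and with the date as a random block. Other alternatives were median centring of the log2 values, no floor, no filter or a stricter filter on dim probe sets, eBayes without a trend or with a robust prior, an F test without moderation, the array letter as a block, only the groups compared in the model, and leaving out each array in turn. Leaving out MOLF A and NZB B together was added after the data had been seen. It leaves lone MOLF and NZB arrays, so the spread then comes from the ILn and LP pairs only. Explanations were weighed against bounds on named values. The requirement that a 95% interval clear such a bound was set after the values had been seen. These intervals came from resampling probe sets or genes, except those of the share of lower calls and the salivary shares, which are exact binomial intervals. All treat probe sets or genes as independent, though they can vary together on an array. They do not measure the spread between arrays, so what they argue against holds for these arrays only.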

Results

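The data were 10 arrays of mouse mammary tumours, 9 of them with a strain name in the title: 1 for FVBn and 2 each for ILn, LP, MOLF and NZB. The series title frames the work as a search for expression signatures of tumour virulence in MMTV-PyMT mice. The comparisons ask which transcripts differ between tumours of the strain names. The measure was quantile normalized log2 intensity, and values are given as mean ± SD of 2 arrays unless stated. FVBn had 1 array and no replicate.

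MOLF A and NZB B stood apart from the other 7 arrays, which resembled each other within and between strains. The correlation across probe sets was 0.974 between the ILn arrays and 0.961 between the LP arrays, against 0.868 for MOLF and 0.852 for NZB. MOLF A and NZB B correlated at 0.927 with each other and at 0.812 to 0.868 with the rest, among which the lowest correlation was 0.931. Strains did not separate cleanly among these 7: LP B correlated at 0.968 with NZB A, above its value with LP A, and FVBn with ILn B at 0.969. More than 2-fold differences within a strain numbered 222 probe sets in ILn, 460 in LP, 1983 in MOLF and 2157 in NZB. A measure of RNA integrity also differed by strain: the log2 ratio of 3' to 5' signal for actin was 0.22 to 0.28 on the FVBn and ILn arrays and 0.60 to 1.12 on the LP, MOLF and NZB arrays. The same ratio for Gapdh was −0.41 to −0.21 on the FVBn and ILn arrays and 0.19 to 0.37 on the LP, MOLF and NZB arrays. The hybridisation spike-ins, in log2 units over the trimmed mean, stood at 2.98 on LP A and 2.95 on MOLF A, both of batch 3, and at 0.86 to 1.23 on the other 7 arrays.

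**Figure D1:**
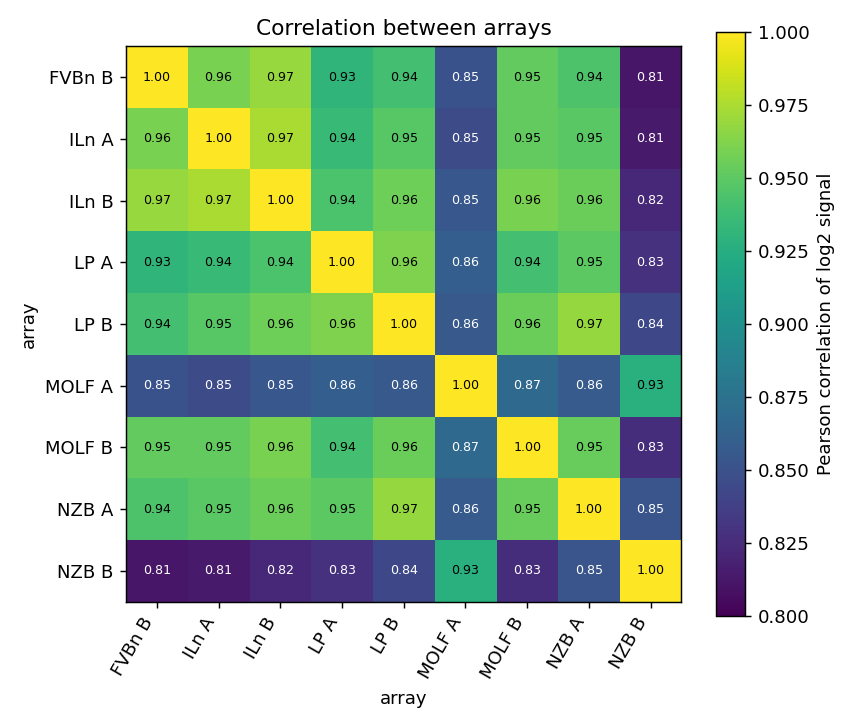
Pearson correlation of log2 signal across probe sets between the 9 arrays with a strain name, coloured from 0.8 to 1. MOLF A and NZB B correlate at 0.927 with each other and at 0.812 to 0.868 with the other 7 arrays.

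Chia1, Amy1, Acta1, Pglyrp1 and Scgb1b27 had the smallest p-values over ILn, LP, MOLF and NZB. Chia1, an acidic chitinase, measured 11.80 ± 0.10 in ILn, 8.20 ± 0.26 in MOLF, 5.89 ± 0.12 in LP and 5.77 ± 0.18 in NZB (adjusted p = 0.000178). Amy1, the salivary amylase that digests starch, measured 11.82 ± 0.32 in ILn and 7.74 ± 0.62 in MOLF and lay at the floor in LP and NZB (adjusted p = 0.000695). Acta1, the actin of skeletal muscle, measured 11.56 ± 0.11 in LP, 11.52 ± 0.04 in NZB, 10.15 ± 0.04 in ILn and 7.84 ± 0.09 in MOLF (adjusted p = 0.000178). Pglyrp1, which binds bacterial peptidoglycan, was lower in ILn (8.0 ± 0.04) than in the other 3 strains (10.26 to 10.51), and Scgb1b27, a secretoglobin, was lowest in MOLF (7.39 ± 0.04, against 9.76 to 10.82), both at an adjusted p of 0.000896. In limma's moderated F test 74 of 9899 probe sets passed, for 56 named genes. Their highest mean lay in ILn for 33, LP for 25, MOLF for 8 and NZB for 8, and their lowest in MOLF for 30, LP for 14, NZB for 9 and ILn for 7, with 14 at the floor in more than 1 strain. With the title date as a block 18 passed. Median centring in place of quantile normalization gave 36, and without MOLF A and NZB B 84 passed, of which 24 were among the 74. Leaving out ILn A or ILn B gave 1, LP A 9, LP B 16, MOLF A 32, MOLF B 35, NZB A 49 and NZB B 30.

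**Figure D2:**
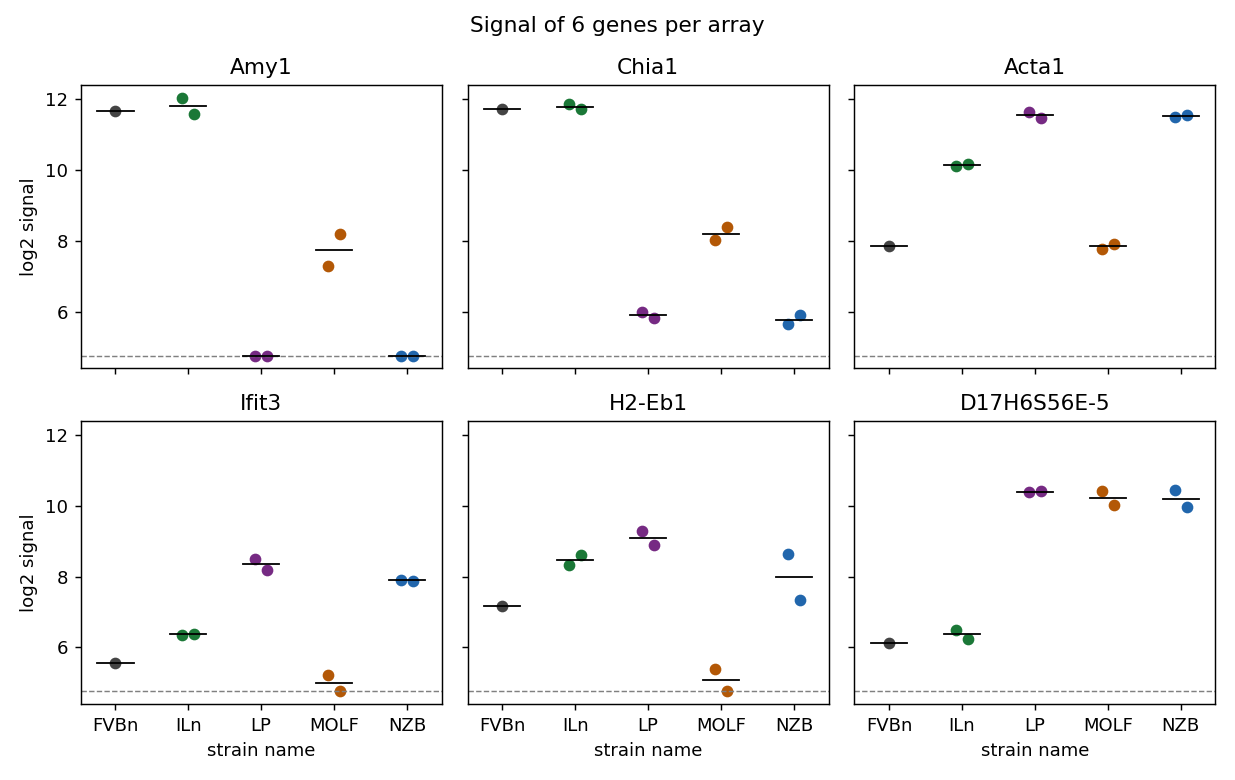
Log2 signal of 6 genes on each of the 9 arrays by strain name, with points for arrays, a bar for the mean and a dashed line at the floor of 4.75. Amy1 and Chia1 are high in FVBn and ILn, Acta1 is highest in LP and NZB, and Ifit3 and H2-Eb1 are lowest in MOLF.

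The largest differences in ILn were higher values of Smr3a, Amy1, Chia1 and Bpifa2 than in LP, MOLF and NZB. Smr3a, a submaxillary gland protein, measured 12.68 ± 0.01 and was at least 69.6-fold higher than the mean of LP, MOLF and NZB (log2 difference 6.12, SE 0.365, adjusted p = 0.000742), and Amy1 was at least 67.2-fold higher (adjusted p = 0.000202). Chia1 was 36.1-fold higher, Bpifa2, the parotid secretory protein, 35.6-fold (13.10 against 11.70 in MOLF, 6.45 in LP and 5.70 in NZB), and Pip, a protein of exocrine secretions, 16.1-fold. Dnase1, a secreted nuclease, was at least 30.4-fold higher and Obp1a, an odorant-binding protein, at least 14.7-fold. Of the 30 measured genes of the salivary gland list, 14 rose in ILn and 0 fell, over LP, MOLF and NZB. The list mean, relative to the 9 arrays, was 1.31 and 1.23 on the ILn arrays and 1.95 on the FVBn array, the 3 arrays with the lowest actin 3' to 5' ratios. It was −0.78 and −0.92 for LP, −0.60 and −0.27 for MOLF and −0.92 and −0.99 for NZB. A single probe set of Ighm, the heavy chain of IgM, was at least 11.7-fold higher, but its other 5 probe sets did not pass, with differences of −0.28 to 1.56. Lower in ILn were D17H6S56E-5 (15.0-fold, 6.37 ± 0.18 against 10.21 to 10.40), Pglyrp1 (5.17-fold) and Saa2, an acute phase protein (1.81-fold, adjusted p = 0.0446, 11.19 against 11.35 in NZB), whose other probe set did not pass. The FVBn array, outside this comparison, was also low in these genes, at 6.13 for D17H6S56E-5, 8.47 for Pglyrp1 and 10.84 for Saa2.

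Among the fixed lists, fibroblast and matrix genes were higher in ILn, with a median of 0.44 over 45 measured genes (camera adjusted p = 7.19e-10, adjusted p = 0.014 with an estimated correlation). Of these 1 rose, or 17 adjusted over the list alone. It was Col3a1, a fibrillar collagen, at 9.78 ± 0.003 and 2.02-fold above the other strains (adjusted p = 0.016). Its other 2 probe sets did not pass. The fibroblast list mean was 0.32 and 0.38 on the ILn arrays and 0.18 on the FVBn array, the 3 arrays with the lowest actin 3' to 5' ratios (0.22 to 0.28) and the highest salivary list means, and −0.31 to −0.07 on the other 6. The macrophage list was also highest on these 3 arrays (0.26, 0.22 and 0.11). The macrophage and myeloid list had a median of 0.28 (0 of 32 rose, 4 adjusted over the list alone, camera adjusted p = 9.58e-05, adjusted p = 0.106 with an estimated correlation). Its members with the smallest p were the chemokine receptor Ccr1 (difference 1.03, adjusted p = 0.184) and the complement gene C1qb (0.76, adjusted p = 0.321, other probe set −0.08). The metastasis-associated list had a median of 0.10 (0 of 45 rose, 2 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.24 with an estimated correlation). In it the matrix protein Postn differed by 0.97 (adjusted p = 0.07) and the protease inhibitor Cst3 by 0.60 (adjusted p = 0.201). Skeletal muscle genes had a median of −0.58 (0 of 28 fell, 4 adjusted over the list alone, camera adjusted p = 1.03e-10, adjusted p = 0.014 with an estimated correlation), with Tnnc2 at −1.11 (adjusted p = 0.103) and Pvalb at −0.71 (adjusted p = 0.283). Interferon response genes had a median of −0.26 (0 of 38 fell, 5 fell and 1 rose adjusted over the list alone, camera adjusted p = 6.38e-05, adjusted p = 0.0422 with an estimated correlation), with Ifitm3 at −0.70 (adjusted p = 0.0742) and Mx1 at −1.36 (adjusted p = 0.184), which lay at the floor in ILn and in MOLF. The neutrophil and acute phase list had a median of −0.33 (1 of 17 fell, Saa2, and 1 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.158 with an estimated correlation). The erythroid list had no call (camera adjusted p = 0.0697), but 2 of 10 measured genes rose, or 3 adjusted over the list alone: the globin chains Hba-a1 (difference 1.74, adjusted p = 0.00336) and Hbb-b2 (2.29, adjusted p = 0.0416), named after their values were seen.

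In limma 40 probe sets passed for ILn against the other strains, 36 higher and 4 lower. With the title date as a block 13 passed (11 higher, 2 lower), and without MOLF A and NZB B 32 passed (22 higher, 10 lower), of which 16 were among the 40. Leaving out ILn A or ILn B left 6, LP A 24 and LP B 23. With the date as a block the mean difference was 0.48 for fibroblast, 0.36 for macrophage, 0.18 for metastasis-associated, −0.56 for muscle and −0.30 for interferon genes, and the medians within batch 4 were 0.51, 0.25, 0.09, −0.69 and −0.44. The neutrophil call was lost with the date as a block (mean −0.21, adjusted p = 0.0651) and without MOLF A and NZB B (adjusted p = 0.202), and its median was −0.02 within batch 4. It was also lost with no filter on dim probe sets (0.251) and without ILn B (0.0544), LP A (0.0516) or NZB A (0.1). The metastasis-associated call was lost without MOLF A and NZB B (adjusted p = 0.127), with the stricter filter (0.139) and without ILn B (0.0756), LP B (0.0738) or NZB A (0.113).

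LP tumours carried more transcript of skeletal muscle and interferon response genes than the mean of ILn, MOLF and NZB. Atp2a1, the calcium pump of fast muscle, was 7.86-fold higher than the mean of ILn, MOLF and NZB (10.08 ± 0.12, log2 difference 2.98, SE 0.331, adjusted p = 0.0219). The fast myosin heavy chains Myh4 and Myh1 were 5.16-fold and 4.77-fold higher, Tnnc2, a fast troponin, 4.17-fold, and Pygm, the muscle glycogen phosphorylase, 3.98-fold. Pvalb, a calcium buffer of fast fibres, was at least 4.67-fold higher, and Acta1 3.31-fold (adjusted p = 0.0037), although NZB had as much Acta1 (11.52 against 11.56). NZB came next for the other muscle genes too, at 8.98 for Atp2a1, 10.07 for Myh4 (10.70 in LP), 8.43 for Myh1 (9.10 in LP) and 9.04 for Tnnc2. Of 28 measured genes of the muscle list 6 rose, or 20 adjusted over the list alone, with a median of 1.37 (camera adjusted p = 4.07e-27, adjusted p = 0.00419 with an estimated correlation). Of 38 interferon response genes 3 rose, or 15 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 1.08e-18, adjusted p = 0.00419 with an estimated correlation). They were the interferon-induced GTPases Gbp3 (3.73-fold, adjusted p = 0.00991) and Gbp2b (at least 2.85-fold) and the ubiquitin-like modifier Isg15 (2.89-fold, adjusted p = 0.0301, 9.66 against 9.19 in NZB). The muscle list mean was 1.05 and 1.0 on the LP arrays, where the interferon list mean was 0.60 and 0.69. The LP and NZB arrays were the highest in both lists and also had the highest actin 3' to 5' ratios (0.94 to 1.12, against 0.22 to 0.78 on the other 5). By the Gapdh ratio they did not stand apart: MOLF B (0.31) lay above LP B (0.26), NZB A (0.25) and NZB B (0.19).

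Antigen presentation genes had a median of 0.41 in LP (camera adjusted p = 5.08e-06, adjusted p = 0.221 with an estimated correlation). Of 26 measured 1 rose, or 4 adjusted over the list alone: B2m, the light chain of MHC class I, at 11.68 ± 0.12 and 1.94-fold above the mean of the others (adjusted p = 0.041), but level with NZB (11.67). The fibroblast list had a median of −0.16 (0 of 45 fell, 1 adjusted over the list alone, camera adjusted p = 0.00136, adjusted p = 0.077 with an estimated correlation), with Col3a1 at −0.62 (adjusted p = 0.163) and Fbln2 at −0.66 (adjusted p = 0.315). Lower in LP were the protease Ctse (3.09-fold, 8.04 against 8.64 in ILn), the milk casein Csn1s2a (2.15-fold, adjusted p = 0.0189) and Fcgbp (2.15-fold, adjusted p = 0.0301), whose second probe set also passed. A probe set of the receptor Notch4 was 3.41-fold higher (12.15 against 11.55 in NZB), while its other probe set differed by −0.12 (adjusted p = 0.92). The second probe sets of Atp2a1, Myh4 and Pvalb differed by 1.53, 0.50 and 0.69 and did not pass, and of the other 2 of Ctse 1 passed. On the salivary list 6 of 30 genes fell in LP.

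In limma 31 probe sets passed for LP, 19 higher and 12 lower. No probe set passed with the title date as a block (0 in limma, 347 at an unadjusted p under 0.05, against 563 without the block), median centring gave 9 (5 higher, 4 lower), and without MOLF A and NZB B 1 passed, which was lower. The array letter as a block gave 9 (3 higher, 6 lower), no filter on dim probe sets gave 37 (18 higher, 19 lower), 0 passed without ILn A, ILn B, LP A or LP B (426, 453, 298 and 548 unadjusted), 7 without MOLF A and 16 without MOLF B, and 3 passed without NZB A (1 higher, 2 lower) and 8 without NZB B (3 higher, 5 lower), so that the balance of directions turned. The list calls held with the date as a block, where the mean difference was 1.12 for muscle, 0.79 for interferon, 0.41 for antigen presentation and −0.15 for fibroblast genes; the medians within batch 4 were 1.31, 0.67, 0.26 and −0.15.

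**Figure D3:**
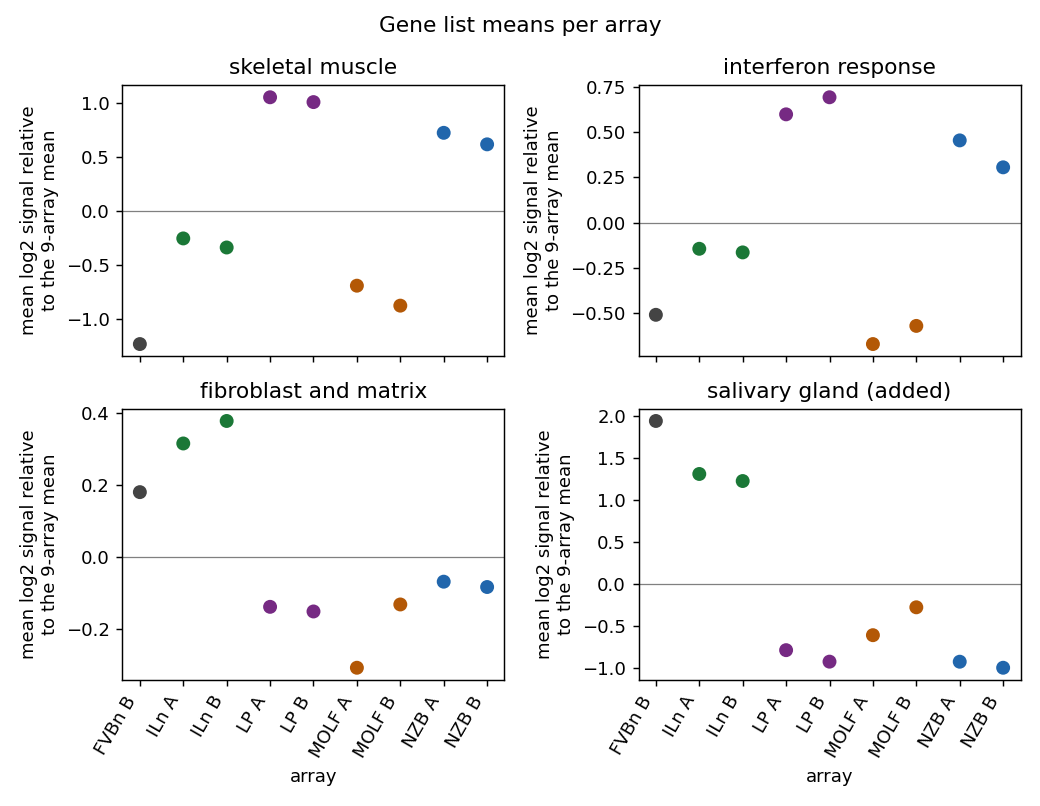
Mean log2 signal of 4 gene lists on each of the 9 arrays, relative to the mean of the 9, with a point per array coloured by strain name. Skeletal muscle and interferon response are high on the LP and NZB arrays, and the salivary gland list is high on the FVBn array (1.95) and the ILn arrays (1.31 and 1.23).

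MOLF tumours had less transcript of skeletal muscle and interferon response genes than ILn, LP and NZB. FVBn, outside this comparison, was lower still in the muscle list (mean −1.23) and level with MOLF in Acta1 (7.86). The interferon list mean of FVBn, −0.51, was close to those of the MOLF arrays. Acta1 fell 9.42-fold (7.84 ± 0.09, adjusted p = 7.51e-05), Atp2a1 9.20-fold, Myh4 7.77-fold, Myh1 6.69-fold, Pygm 6.39-fold and Myl1, a muscle myosin light chain, 4.57-fold. Scgb1b27 fell 6.81-fold (adjusted p = 0.000501), H2-Eb1, a chain of MHC class II, 10.9-fold (5.07 ± 0.45, log2 difference −3.44, SE 0.373, adjusted p = 0.0141), and B2m 2.76-fold (adjusted p = 0.00515). Of 38 interferon genes 5 fell, or 20 adjusted over the list alone, with a median of −0.86 (camera adjusted p = 3.04e-21, adjusted p = 0.00323 with an estimated correlation): Ifit3, an interferon-induced antiviral protein, 5.83-fold, Gbp3 4.19-fold, Iigp1, an immunity-related GTPase, 3.50-fold and Isg15 2.95-fold were the largest. Of 28 muscle genes 6 fell, or 19 adjusted over the list alone, with a median of −1.35 (camera adjusted p = 2.86e-23, adjusted p = 0.00323 with an estimated correlation). The muscle list mean was −0.69 and −0.87 on the MOLF arrays, where the interferon list mean was −0.67 and −0.57. Of 26 antigen presentation genes 2 fell, H2-Eb1 and B2m, or 11 adjusted over the list alone, with a median of −0.53 (camera adjusted p = 1.09e-11, adjusted p = 0.0846 with an estimated correlation).

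Higher in MOLF were a probe set of Pdxdc1 (at least 11.4-fold), Mup5, a major urinary protein (at least 5.87-fold over the mean, at 9.59 against 9.10 in ILn, 7.26 in LP and the floor in NZB), C1qtnf1 (4.37-fold), Ctse (3.59-fold), Saa2 (2.13-fold, 12.65 against 12.14 in LP), the ribosomal protein gene Rpl13a (1.85-fold, adjusted p = 0.0496) and a probe set of the kinase Map3k1 (at least 3.46-fold). Another named by the rule carries a microRNA symbol, and its value is not given, since the match to that RNA was not made. The other 2 probe sets of Pdxdc1 differed by −0.88 and −0.38 and those of Map3k1 by −0.28 and 0.73, none past the test, and 1 of the other 2 of Ctse passed. The other probe sets of C1qtnf1 (1.81 and 0.37), Saa2 (1.93), Atp2a1 (−2.03), Iigp1 (−1.37) and Myh4 (0.46) did not pass. The fibroblast list had a median of −0.19 (0 of 45 fell, 0 adjusted over the list alone, camera adjusted p = 0.000757, adjusted p = 0.067 with an estimated correlation), with Eln at −1.11 (adjusted p = 0.194, other probe set 0.73) and Mmp2 at −0.73 (adjusted p = 0.497). The macrophage list had a median of −0.20 (0 of 32 fell, 0 adjusted over the list alone, camera adjusted p = 0.00835, adjusted p = 0.196 with an estimated correlation), with Mpeg1 at −0.90 (adjusted p = 0.272) and C1qb at −0.66 (adjusted p = 0.439, other probe set −0.01). That call was lost without MOLF B (adjusted p = 0.364). On the salivary list 1 of 30 genes rose and 2 fell.

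In limma 41 probe sets passed for MOLF, 13 higher and 28 lower. With the title date as a block 6 passed (0 higher, 6 lower), median centring gave 23 (6 higher, 17 lower), and without MOLF A and NZB B 50 passed (44 higher, 6 lower), of which 8 were among the 41, so that the balance of directions turned. Leaving out ILn A gave 3, ILn B 4, LP A 5, LP B 6, MOLF A 4, MOLF B 18, NZB A 17 and NZB B 19. With the date as a block the list calls held at mean differences of −1.29 for muscle, −0.90 for interferon, −0.60 for antigen presentation, −0.26 for macrophage and −0.25 for fibroblast genes; the medians within batch 4 were −1.11, −0.69, −0.37, −0.31 and −0.17.

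NZB tumours had less Mup5 and Sat1 and more Csn1s2a and Acta1 than the mean of ILn, LP and MOLF. Mup5 lay at the floor on both NZB arrays and was at least 14.9-fold lower (log2 difference −3.90, SE 0.21, adjusted p = 0.00206), and Sat1, which acetylates polyamines, was 2.13-fold lower (9.22 ± 0.10, adjusted p = 0.0485). Csn1s2a was 2.53-fold higher (10.76 ± 0.09, adjusted p = 0.0079), and a probe set of H2-D1, an MHC class I heavy chain, was 4.36-fold higher (10.52 ± 0.02, adjusted p = 0.0485), while its other 2 probe sets differed by 0.25 and 0.79 and did not pass. Acta1 rose 3.18-fold (adjusted p = 0.00291) over that mean, and was no higher than in LP (11.52 against 11.56). Of 28 muscle genes 1 rose, or 13 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 4.38e-10, adjusted p = 0.0301 with an estimated correlation). The interferon list had a median of 0.38 (0 of 38 rose, 8 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.77e-07, adjusted p = 0.0301 with an estimated correlation), with Iigp1 at 1.09 (adjusted p = 0.156) and Mx1, an antiviral GTPase, at 1.35, a bound (adjusted p = 0.234). The muscle list mean was 0.72 and 0.61 on the NZB arrays, where the interferon list mean was 0.45 and 0.31 and the actin 3' to 5' ratio 0.96 and 1.03. On the salivary list 4 of 30 genes fell.

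In limma 10 probe sets passed for NZB, 4 higher and 6 lower. A block for the title date left 0 in limma (487 at an unadjusted p under 0.05, against 832 without the block), median centring gave 4 (0 higher, 4 lower), no filter on dim probe sets 21 and the stricter filter 27. Leaving out NZB A gave 36, ILn A or ILn B 0 (587 and 640 unadjusted), MOLF B 5 and LP A, LP B or NZB B 4 each, and without MOLF A and NZB B 22 passed (18 higher, 4 lower), of which 3 were among the 10, so that the balance of directions turned. The list calls held with the date as a block, at mean differences of 0.73 for muscle and 0.41 for interferon genes, and the medians within batch 4 were 0.90 and 0.49.

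The FVBn tumour array had higher levels of Mucl1, Mucl2, Prol1 and Klk1 than each of the 4 other strain names, and lower levels of muscle genes than their mean. Mucl1 and Mucl2, mucin-like secreted proteins, were at least 137-fold and at least 123-fold higher in FVBn than in the mean of the other 4 (11.86 and 12.57, adjusted p = 0.000269 and 0.000846). Prol1, a proline-rich secreted protein, was 63.5-fold higher (13.08), and Klk1, a glandular kallikrein, at least 27.1-fold. Bpifa2 was 17.0-fold above the mean of the 4, but ILn was close to FVBn (13.10 ± 0.03 against 13.32) and MOLF stood at 11.70, with 6.45 in LP and 5.70 in NZB. Of 30 salivary list genes 12 were lower in the 4 strains. Higher in the mean of the 4 strains were Myh4 (16.2-fold, adjusted p = 0.0028), Atp2a1 and Myh1 (at least 8.55-fold and 6.32-fold), Acta1 (5.28-fold), Myl1 (4.92-fold) and D17H6S56E-5 (9.01-fold, adjusted p = 0.00273). These folds did not hold in each strain: Acta1 was 7.84 in MOLF against 7.86 in FVBn, D17H6S56E-5 was 6.37 in ILn against 6.13 in FVBn, and the 5 muscle genes were highest in LP and NZB. Of 28 muscle genes 5 rose, or 12 adjusted over the list alone, with a median of 0.92 (camera adjusted p = 2.17e-35, adjusted p = 0.00262 with an estimated correlation). The muscle list mean was −1.23 and the interferon list mean −0.51 on the FVBn array, whose actin 3' to 5' ratio was 0.22 (0.22 to 1.12 on the 8 others).

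The interferon list had a median of 0.50 in the 4 strains over FVBn (0 of 38 rose, 1 adjusted over the list alone, camera adjusted p = 1.9e-12, adjusted p = 0.00949 with an estimated correlation), with Ifi47 at 1.94 (adjusted p = 0.198) and Iigp1 at 1.07 (adjusted p = 0.456). In 4 further lists no member passed, over all probe sets or adjusted over the list alone (0 each). Antigen presentation had a median of 0.29 (camera adjusted p = 1.71e-05, adjusted p = 0.194 with an estimated correlation), with Psmb8 at 0.68 and H2-K1 at 0.42. Adipocyte genes had a median of 0.43 (camera adjusted p = 0.00481, adjusted p = 0.0982 with an estimated correlation), with Car3 at 0.97 and Pnpla2 at 0.47. Hypoxia and glycolysis genes had a median of −0.28 and fibroblast genes of −0.16 (camera adjusted p = 0.00425 and adjusted p = 0.0982 with an estimated correlation for each). Their members with the smallest p were the angiogenic factor Vegfa (−1.21) and Adm (−0.88, a bound), and Lum (−0.74) and Col3a1 (−0.64). The adjusted p-values of these 8 genes lay between 0.456 and 0.999.

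In limma 31 probe sets passed for the 4 strains against FVBn, 9 higher and 22 lower; the comparison has 1 FVBn array and no replicate check on it. With the title date as a block 10 passed (3 higher, 7 lower), no filter on dim probe sets gave 102 (18 higher, 84 lower), and without MOLF A and NZB B 25 passed (2 higher, 23 lower). Leaving out ILn A or ILn B gave 17, LP A 15 and LP B 16. With the date as a block the list calls held, at mean differences of 1.36 for muscle, 0.61 for interferon, 0.31 for antigen presentation, 0.30 for adipocyte, −0.21 for hypoxia and −0.17 for fibroblast genes; the medians within batch 4 were 0.96, 0.52, 0.29, 0.31, −0.21 and −0.17. The hypoxia call was lost with the stricter filter on dim probe sets (adjusted p = 0.0908). The other probe set of Mucl2 passed, a second of Col3a1 differed by 0.05, and those of Atp2a1 (2.86) and Myh4 (−0.53) did not.

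ILn and NZB each had 1 array in batch 2 and 1 in batch 4, so a shared effect of the date cancels between them. Bpifa2 was 169-fold higher in ILn (13.10 ± 0.03 against 5.70 ± 0.46, log2 difference 7.40, SE 0.44, adjusted p = 0.00069), Smr3a 139.8-fold and Amy1 at least 134-fold. Of 30 salivary list genes 11 rose. Lower in ILn were D17H6S56E-5 (14.3-fold), a probe set of H2-D1 (6.04-fold) and Pglyrp1 (4.80-fold, adjusted p = 0.00069). Acta1 fell 2.59-fold (adjusted p = 0.0101), the 1 of 28 muscle genes past the test, with 13 adjusted over the list alone and a median of −1.07 (camera adjusted p = 9.43e-13, adjusted p = 0.0199 with an estimated correlation). Interferon genes had a median of −0.68 (0 of 38 fell, 11 adjusted over the list alone, camera adjusted p = 5.59e-07, adjusted p = 0.03 with an estimated correlation), with Mx1 at −2.03, a bound (adjusted p = 0.0859), and Isg15 at −1.33 (adjusted p = 0.0895). The fibroblast list had a median of 0.39 (0 of 45 rose; 10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000271, adjusted p = 0.0506 with an estimated correlation), with Lum at 1.51 (adjusted p = 0.111) and Col3a1 at 0.98 (adjusted p = 0.0559, a second probe set −0.35). This call was lost without NZB A (adjusted p = 0.16). The actin 3' to 5' ratio was 0.22 and 0.28 on the ILn arrays and 0.96 and 1.03 on the NZB arrays. The macrophage list had a median of 0.34 (0 of 32 rose, 0 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.201 with an estimated correlation), with Ccr1 at 1.02 and C1qa at 0.75. In the erythroid list, which had no call (camera adjusted p = 0.124), 2 of 10 rose, or 4 adjusted over the list alone: Hba-a1 (1.52, adjusted p = 0.0231) and the carbonic anhydrase Car2 (1.16, adjusted p = 0.0488), named after their values were seen. The other probe sets of H2-D1 (−0.10 and −0.86) and Pglyrp1 (−1.51) did not pass.

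In limma 34 probe sets passed for ILn against NZB, 28 higher and 6 lower. With only these 4 arrays in the model 0 passed in limma (817 at an unadjusted p under 0.05), and 6 passed without ILn A, 5 without ILn B, 11 without LP A, 11 without LP B and 10 without NZB B. The title date as a block gave 16 (11 higher, 5 lower), median centring gave 26 (25 higher, 1 lower), and without MOLF A and NZB B 50 passed (15 higher, 35 lower), so that the balance of directions turned. The medians in batches 2 and 4 were −0.84 and −1.28 for muscle, −0.58 and −0.74 for interferon, 0.26 and 0.63 for fibroblast and 0.51 and 0.20 for macrophage genes, and the list calls held with the date as a block (mean differences −0.96, −0.53, 0.42 and 0.37).

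LP and MOLF each had 1 array in batch 3 and 1 in batch 4, with actin 3' to 5' ratios of 1.12 and 0.94 for LP and 0.78 and 0.60 for MOLF. The Gapdh ratios overlapped, at 0.37 and 0.26 for LP and 0.20 and 0.31 for MOLF. Muscle and interferon genes were higher in LP, among them Atp2a1 24.8-fold (10.08 ± 0.12 against 5.45 ± 0.83, log2 difference 4.63, SE 0.405, adjusted p = 0.00574) and Myh4 15.9-fold (adjusted p = 0.00401). Of 28 muscle genes 8 rose, or 20 adjusted over the list alone, with a median of 2.00 (camera adjusted p = 3.34e-29, adjusted p = 0.00224 with an estimated correlation), among them Myh1 (13.4-fold), Acta1 (13.2-fold) and Actn3 (9.66-fold). Of 38 interferon genes 4 rose, or 19 adjusted over the list alone, with a median of 1.09 (camera adjusted p = 1.74e-25, adjusted p = 0.00224 with an estimated correlation): Ifit3 (10.3-fold), Gbp3 (7.87-fold), Isg15 (4.99-fold) and Iigp1 (4.40-fold). Of 26 antigen presentation genes 2 rose, H2-Eb1 (16.1-fold, adjusted p = 0.0156) and B2m (3.53-fold), or 12 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 6.58e-11, adjusted p = 0.127 with an estimated correlation). Lower in LP were Bpifa2 (38.0-fold), Smr3a (at least 24.4-fold) and a probe set of Pdxdc1 (10.9-fold), whose other 2 differed by 0.97 and 0.26. Of the salivary list 2 of 30 genes rose and 4 fell. The other probe sets of Atp2a1 (2.67), Iigp1 (2.21), Actn3 (1.09) and Myh4 (0.03) did not pass.

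In limma 44 probe sets passed for LP against MOLF, 30 higher and 14 lower. With only these 4 arrays in the model 0 passed in limma (596 at an unadjusted p under 0.05), and 2 passed without LP A, 1 without LP B, 9 without ILn A or ILn B, 20 without MOLF A, 26 without MOLF B and 28 without NZB B. The title date as a block gave 33 (24 higher, 9 lower), median centring gave 27 (19 higher, 8 lower), and without MOLF A and NZB B 63 passed (13 higher, 50 lower), so that the balance of directions turned. The medians in batches 3 and 4 were 1.91 and 1.79 for muscle, 1.24 and 1.10 for interferon and 0.78 and 0.44 for antigen presentation genes, and the list calls held with the date as a block (mean differences 1.81, 1.26 and 0.76).

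In 10 of the 19 lists no comparison passed. The smallest camera adjusted p over the 7 comparisons was 0.0957 for proliferation and for milk and alveolar differentiation, 0.13 for luminal epithelium, 0.263 for basal and myoepithelial cells, 0.248 for T and NK cells and 0.198 for B and plasma cells. It was 0.0658 for endothelium, 0.0697 for erythroid cells, 0.164 for cholesterol and fatty acid synthesis and 0.466 for immediate early and heat shock genes. The medians in those comparisons lay between −0.27 for endothelium in MOLF and 0.18 for B and plasma cell genes in the 4 strains against FVBn. Single members of such lists passed, named after their values were seen. In MOLF the tropomyosin Tpm2 (−1.75, adjusted p = 0.0295), the keratin Krt19 (−1.19, adjusted p = 0.0274) and the milk protein Ltf (−0.88, adjusted p = 0.026) were lower, 1 each of 13 basal, 20 luminal and 21 milk genes (1, 2 and 2 fell and 0, 1 and 0 rose adjusted over the list alone). The other probe sets of Tpm2 (0.67) and Krt19 (−0.70) did not pass. Over the strains Tpm2 ran in the order of the muscle list, with differences of 1.45 in LP, 0.84 in NZB and −0.54 in ILn. The median of the basal list in MOLF was 0.10, so the Tpm2 call does not show a change in basal genes. In LP the chemokine Ccl5 was higher (a bound of 1.62, adjusted p = 0.0222), the 1 of 20 T and NK cell genes past the test (1 adjusted over the list alone). Of the 21 milk genes Csn1s2a fell in LP (3 rose and 4 fell adjusted over the list alone) and rose in NZB (5 rose and 2 fell). In LP against MOLF Ltf (1.09, adjusted p = 0.0215), Tpm2 (2.40, adjusted p = 0.0182) and Ccl5 (a bound of 1.62, adjusted p = 0.0348) rose, with 3 milk genes up and 5 down, 1 basal gene up and 1 T and NK cell gene up adjusted over the list alone.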

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

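The tests of a wrong strain label, of samples of other strains, of immune cells and of muscle transcripts, the salivary gland list and the genes left out of its test, the settings without MOLF A and NZB B, and the requirement that a 95% interval clear a bound were chosen only after the results were seen. On the values alone, without that requirement, the share of lower calls in MOLF (0.683, over 0.6) would count for sequence variants, the median over other probe sets in MOLF (0.592, over 0.5) against them, and the salivary share (0.2, under 0.5) against salivary gland tissue. So would the share of NZB B (0.793, over 0.5) against a wrong label on it, and an interferon mean of −0.51 against muscle tissue. However, the balance of lower and higher calls in MOLF turned without MOLF A and NZB B, so that share does not stand by itself. Several genes behind the salivary share could show little either way, and leaving out genes already seen favoured a low share in advance.

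The array whose title names no strain, which entered no comparison, lay above all 9 strain arrays by more than their whole range in 6 gene lists. Its list mean, as log2 signal relative to the mean of the 9 arrays, was 2.67 for adipocytes (−0.29 to 0.25 on the 9 arrays) and 1.69 for endothelium (−0.26 to 0.19). It was 1.22 for B and plasma cells (−0.30 to 0.20), 1.16 for basal and myoepithelial cells (−0.10 to 0.17), 1.06 for erythroid cells (−0.25 to 0.25) and 1.03 for T and NK cells (−0.21 to 0.32). No biological explanation was tested, since the labels give this array no group.

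The 74 probe sets past the strain F test were set against other ways to put the same 8 arrays in 4 pairs. Of 100 drawn from the 105 ways, the real one included, 16 gave as many, and the highest of the others gave 1532, so chance cannot be excluded by this count. The 15 others with as many calls each paired MOLF A with NZB B, and where these were apart the highest count was 30. The count of 1532 came from such a pairing, so it points to the likeness of MOLF A and NZB B, and it does not show the source of that likeness. The F test with the title date as a block gave 18.

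MOLF A and NZB B, of different strain names and different title dates, correlated more with each other than with their partners. A wrong strain label on MOLF A is argued against, because over 38 probe sets that set MOLF B apart it showed a median of 0.830 (95% interval 0.574 to 0.915) of the deviation of MOLF B, and more of it than each of the 7 arrays of other strains, by 0.299 at the lowest bound (FVBn, 0.0846 to 0.590). A sample of another strain of the series on NZB B is also argued against: it showed more of the deviation of NZB A than each of the 5 arrays of FVBn, ILn and LP, by 0.551 at the lowest bound (LP A, 0.207 to 0.772), and over 508 probe sets on which NZB A and MOLF B differed by over 1 log2 unit it lay 0.144 of the way from NZB A to MOLF B (0.0905 to 0.228, against 0.759 for MOLF A), where a MOLF sample was to lie at 0.5 or more. Another 2 tests, run before that one, left a MOLF sample narrowly open (a share of 0.0599 of the deviation of MOLF B, −0.0302 to 0.288, against a bound of 0.25, and an excess over MOLF A of 0.531, 0 to 0.844), and a sample from outside the series stays open, since the share of NZB B in the deviation of NZB A was 0.793 (0.340 to 1), above the 0.25 a wrong label was to stay under but reaching below 0.5. Noise at dim probe sets alone is argued against, because in the brightest 2475 probe sets the SD within the MOLF pair was 1.58 times that of ILn (1.51 to 1.66). A probe-set-specific effect of hybridisation or scanning is a candidate explanation, because over 439 genes with a pair of bright probe sets the difference of these 2 arrays from their partners correlated at 0.0263 (−0.0909 to 0.145) between the probe sets of a pair, against 0.415 for the difference between LP and ILn. For these genes that low correlation also argues against a difference in transcript levels between the tumours as the main source, since it would move both probe sets. A biological difference was not tested in another way.

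Interferon genes were high in LP and low in MOLF, and of the 41 calls in MOLF a share of 0.683 was lower (0.519 to 0.819, against 0.6 in NZB), with 13 lower and 13 higher outside the muscle, interferon and antigen presentation lists. The balance turned to mostly higher calls without MOLF A and NZB B, a setting with a lone MOLF array, so the share depends on which arrays are used. Sequence variants under probes designed on another strain may contribute to lower calls: other probe sets of the same genes showed a median of 0.592 of the difference, above the bound of 0.5 that counts against variants, but with an interval of −0.156 to 0.760 over 7 genes. More immune cells in LP stay open on 1 list, since LP exceeded MOLF by 0.04 for T and NK cells (upper bound 0.16), 0.18 for macrophages (0.33) and 0.23 for B and plasma cells (0.55), against 1.09 for interferon genes, and the last of these bounds alone reached 0.5 of that value. Muscle tissue stays open too: the LP and NZB arrays were highest in both the muscle and the interferon list and the MOLF and FVBn arrays lowest. The muscle and interferon list means correlated at 0.969 over the 9 arrays and at 0.985 over the 5 arrays of batch 4. Both follow the strain, so this does not separate muscle from strain. The LP and NZB arrays also had the highest actin 3' to 5' ratios, but not the highest Gapdh ratios, and an effect of RNA integrity was not tested. The array richest in muscle transcripts (no strain name) had an interferon mean of −0.51 against 0.65 in LP, but is a single array. A difference between strains also stays open and was not tested.

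Salivary gland genes were high in FVBn and ILn, and some of them in MOLF, with levels of 13.32 in FVBn, 13.10 in ILn and 11.70 in MOLF for Bpifa2 and of 11.67, 11.82 and 7.74 for Amy1. The hypothesis of salivary gland tissue in the tumour pieces was put to 10 list genes whose values had not been looked at, after 4 of 14 first taken as such proved to have been displayed and were left out (5 of the 14, a share of 0.357 with an interval of 0.128 to 0.649, were higher in FVBn and ILn). Of the 10 genes 2, a share of 0.2 (exact 95% interval 0.0252 to 0.556), were higher in FVBn and ILn than in LP and NZB, against 0.197 of all genes. The share lay below the 0.8 set in advance for tissue in the pieces and its interval excludes 0.8, but it reaches above 0.5, the bound below which tissue would be argued against. The list was added after the leading genes had been seen, so leaving out seen genes took leading genes out of the test. That favoured a low share in advance, so the share does not count against tissue. Several of the 10 genes could also show little either way. Kcnn4, Slc12a2 and Pigr measured 10.05 or more in every strain, also in LP and NZB. Cftr, Dmbt1 and Azgp1 measured 5.92 or less in every strain, near the floor. The test therefore cannot decide, and salivary gland tissue stays open. Of the 54 list genes 0 are in another list and 20 had been seen, 12 of the 30 measured lay above the floor on all 9 arrays, and a difference between strains stays open as untested.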

How the results depend on the processing

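Leaving out MOLF A and NZB B together was chosen only after the results were seen. In that setting calls for MOLF or NZB rest on unreplicated arrays and on the spread of the ILn and LP pairs, so its counts and balances carry that limit. No named gene or list call changed direction under any setting run. For genes named for large differences this checks little, since they were chosen for arrays that do not overlap. The balance of higher and lower calls turned for LP, MOLF, NZB, ILn against NZB and LP against MOLF without those 2 arrays. For LP it also turned with the letter block (3 higher, 6 lower), with no filter on dim probe sets (18 and 19), without NZB A (1 and 2) and without NZB B (3 and 5). Counts are of probe sets past limma's adjusted threshold, and the cause of a shift was not tested except where fewer arrays or degrees of freedom give it. With the title date as a block the F test gave 18, ILn 13, LP 0 (347 at an unadjusted p under 0.05), MOLF 6, NZB 0 (487), FVBn 10 and ILn against NZB 16; the block leaves fewer degrees of freedom. Median centring gave 36 for the F test, 9 for LP, 23 for MOLF, 4 for NZB and 27 for LP against MOLF. No filter on dim probe sets gave 21 for NZB and 102 for FVBn, and the stricter filter 27 for NZB. Without an intensity trend the F test gave 48 and NZB 4, and without moderation the F test gave 44, of which 23 were among the 74. The date as a random block gave 58 for ILn against NZB. With only the 4 arrays of a pair of strains in the model, ILn against NZB gave 0 (817 unadjusted) and LP against MOLF 0 (596). These models have fewer arrays, and the wider NZB or MOLF pair weighs more in their spread. These effects were not separated. Without MOLF A and NZB B, LP gave 1 and NZB 22. No floor and a robust prior moved no count by over 1.5 times. The array letter as a replicate block gave 31 for the F test, 9 for LP, 26 for MOLF, 20 for FVBn and 19 for ILn against NZB; deviations of same-lettered arrays correlated between −0.707 and 0.131 over pairs of strains, so the letters do not pair the arrays. The called probe sets all kept their sign within each batch that held the groups compared, which their selection on the same arrays nearly fixes, so it checks nothing. Of 30 list calls, 30 held with median centring, no floor or the letter block, 29 with the date block, 28 without MOLF A and NZB B, 23 with fry, 15 with an estimated correlation, 28 with the stricter filter and 29 with no filter. Leaving out single arrays ended 3 list calls without NZB A, 2 without ILn B and 1 each without LP A, LP B and MOLF B, and 0 without ILn A, MOLF A and NZB B, or without FVBn, where 24 could be tested. Of the named gene values, 70 kept their side of the threshold and 47 lost it with the date block, 85 and 32 with median centring, and 61 and 56 without MOLF A and NZB B. Without ILn A and without ILn B 55 kept it and 62 lost it in each case, without LP A 62 and 55, without LP B 61 and 56, and without MOLF A 75 and 42; other single arrays lost 1 to 33. The 4 strains against FVBn cannot be run without the FVBn array. The floor at an intensity of 27.0 limits folds of dim probe sets to bounds.

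Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 1 to 80 for the F test, 6 to 43 for ILn, 0 to 30 for LP, 3 to 42 for MOLF, 0 to 36 for NZB, 15 to 31 for FVBn, 5 to 45 for ILn against NZB and 1 to 44 for LP against MOLF. In the order ILn A, ILn B, LP A, LP B, MOLF A, MOLF B, NZB A and NZB B, the F test gave 1, 1, 9, 16, 32, 35, 49 and 30, LP 0, 0, 0, 0, 7, 16, 3 and 8 (426, 453, 298 and 548 unadjusted at the zeros), and MOLF 3, 4, 5, 6, 4, 18, 17 and 19. In that order NZB gave 0, 0, 4, 4, 10, 5, 36 and 4 (587 and 640 unadjusted at the zeros), ILn against NZB 6, 5, 11, 11, 25, 28, 45 and 10, and LP against MOLF 9, 9, 2, 1, 20, 26, 34 and 28. ILn gave 6 without ILn A, 6 without ILn B, 24 without LP A and 23 without LP B, and FVBn gave 17, 17, 15 and 16 without them. Without the FVBn array the counts stayed within 1.5 times.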

Other observations

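The array with no strain name in its title had high list means for muscle and connective tissue and low ones for proliferation, milk and luminal epithelium, while basal and myoepithelial genes were high (1.16) and the milk gene Csn1s2a, at 11.55, lay above the 9 strain arrays (8.89 to 10.82). Its list mean, as log2 signal relative to the mean of the 9 strain arrays, was 2.45 for skeletal muscle (−1.23 to 1.05 on the 9 arrays), 0.96 for fibroblasts and matrix (−0.31 to 0.38) and 0.70 for antigen presentation (−0.55 to 0.32). It was −1.0 for proliferation (−0.28 to 0.12), −0.95 for milk and alveolar differentiation (−0.17 to 0.16), −0.76 for luminal epithelium (−0.09 to 0.11) and −1.41 for neutrophils and the acute phase (−0.19 to 0.31). The salivary gland list, chosen only after the leading genes were seen, had a mean of −1.52 (−0.99 to 1.95). The correlation of this array with the 9 strain arrays lay between 0.763 and 0.869, highest with LP B.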
